A study of Homo sapiens with 9 samples.

How the data were processed

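The series measured total RNA from 9 samples of the human malignant melanoma line labelled A375-BRAFV600E/NRASQ61 on the nCounter platform, which counts fluorescent barcodes hybridised to each target transcript without amplification. Per the labels' protocols, RNA was extracted from cell lysates with a column kit, from cells that had undergone at most 5 population doublings since they were thawed. The samples fall into 3 groups by the genotype in their labels.

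The authors deposited 1 table for the whole series, whose values its name describes as normalized. How the values were normalized, which software was used and whether a background threshold was applied are not given in the sources used here. The table has 784 rows, of which 740 are of the endogenous class, 30 of the housekeeping class, 6 are positive controls and 8 are negative controls. Other text columns, deposited beside the values, give each probe's gene symbol, target transcript, older names, class and target sequence.

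The 9 columns of per-sample values carry serial headings, and 0 of these headings occur in any title, description or other label of a sample. A serial heading gives neither a genotype nor a clone. Column order is no label, and assigning the columns by the values in them would have presumed the outcome of the comparisons, so none of the 9 columns was used. The headings and value ranges had been inspected before this was decided. For this reason no expression level, depth, fold change, error or p-value is reported. The design fixed before the data were examined was a limma fit of log2 values over the 3 groups, with 24 gene lists, a rule for the genes to be named and a set of alternative settings. The rule for named genes ranked genes called by that fit and took the members of each list with the smallest p. With no fit it selected no gene, and the genes named are members of the fixed lists, chosen as examples from the panel's text columns.

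The text columns were read with Python 3.11.15. Target transcripts were matched, without version numbers, to a RefSeq gene table for GRCh38.p14, used for names only. Of the 770 gene rows, 747 matched by transcript accession, and 15 of these now carry another symbol. The other 23 matched by symbol alone. The knocked-out gene was searched for by its symbol, by older names that are no other gene's symbol, and by its transcript accessions. The members of each fixed list were matched by current or older symbol. All 296065 pairs of target sequences were searched for a shared stretch of at least 25 bases on the same strand. This search was tested on simulated random sequences. It found 13 of 13 pairs planted with a stretch of at least 25 bases. It returned 0 others, and so none of the pairs planted with a shorter stretch. The planted stretches were exact, so the test checked the search itself and not its reach for similar targets with mismatches. Plots were drawn with matplotlib 3.10.9.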

Results

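The study asked how the expression of tumour progression genes in a melanoma line differs when melanotransferrin (MELTF), a membrane-bound member of the transferrin family, is knocked out. The labels name the cells A375-BRAFV600E/NRASQ61, a form of A375, an established human malignant melanoma line that carries an activating BRAF mutation. The labels do not say which change, if any, NRASQ61 stands for. The samples came from 3 lines, with 3 samples each. One line was wildtype for MELTF, and the others were the knockout clones A7 and A18. The labels do not say whether the 3 samples of a line came from separate cultures.

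The design implies 3 pairwise comparisons, namely clone A7 with wildtype, clone A18 with wildtype, and the 2 clones with each other. A comparison of the mean of both clones with wildtype was also fixed in advance. None of these was made. The 9 columns of expression values are not tied to genotypes by any label used here, so no gene is reported as higher or lower in any line. What follows describes which transcripts the panel was built to measure.

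The panel held probes for 770 transcripts, 740 of the endogenous class and 30 of the housekeeping class, the same total as the labels state. No row named MELTF by symbol, older name or transcript accession, so the transcript of the knocked-out gene was not analysed here and could not serve as a check of the genotype labels. Of the 24 gene lists fixed before the data were examined, 23 had at least 3 targeted members. A test required at least 3 members that also passed a filter on low values, and reference genes were to be tested apart. How many lists could have been tested is therefore not known. A total of 323 endogenous genes belonged to at least 1 list and 417 to none. The lists were drawn up from the panel's subject and the cell type, so their coverage was partly built in. The counts below are shares of these lists, not of whole gene families.

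The epithelial and mesenchymal lists were covered broadly. Probes targeted 29 of the 46 epithelial and junction genes, among them CDH1, which encodes E-cadherin, EPCAM, the claudins CLDN1, CLDN3, CLDN4 and CLDN7, and the splicing factor ESRP1. Probes targeted 15 of the 23 mesenchymal genes, including CDH2, which encodes N-cadherin, VIM, which encodes vimentin, and the transcription factors SNAI1, SNAI2, TWIST1, TWIST2, ZEB1 and ZEB2.

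The lists of matrix genes, integrins, proteases and protease inhibitors were also covered, in varying shares. The panel targeted 28 of 44 matrix glycoprotein and proteoglycan genes, such as FN1, SPARC, TNC and THBS1, and 14 of 24 basement membrane genes, such as COL4A1 and HSPG2. Of the listed fibrillar and interstitial collagens, 9 of 24 had a probe. Probes targeted 17 of the 25 listed integrins and 18 of the 33 listed metalloproteinases, the latter including MMP1, MMP2, MMP9, MMP14 and ADAM17. In the list of plasminogen activation and protease inhibitors, 13 of 29 genes had a probe. They included PLAU, which encodes urokinase, its receptor PLAUR, and the metalloproteinase inhibitors TIMP1 and TIMP2.

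Signalling and stress lists were covered unevenly. TGF-beta and BMP signalling had more targeted genes than any other list, 32 of 58, among them TGFB1, TGFB2, TGFBR2 and SMAD3. In the list of secreted angiogenic factors, 26 of 41 genes had a probe, including VEGFA, VEGFB and VEGFC. Despite its name the list also holds genes of membrane-bound ligands, DLL4 and JAG1. The panel targeted 30 of the 45 genes in the metastasis suppressor list, such as NME1, KISS1, CD82 and BRMS1. The targeted members also included MTA1, ROCK1, CD44 and CDH11, the last of which was in the mesenchymal list too. A place in this list does not by itself mark a gene as a suppressor. The panel also targeted 23 of the 43 listed receptor tyrosine kinases and co-receptors. It further targeted 22 of the 42 listed hypoxia response genes and 22 of the 49 listed chemokines and cytokines. In contrast, the Notch list had 5 of 22 genes, the Wnt list 6 of 40 and the MAPK output list 6 of 25. The targeted Notch list members were DLL4, JAG1, NOTCH1, RBL1 and RBPJ, of which DLL4 and JAG1 were also counted in the angiogenic list. RBL1 was counted because the list holds it, not as an established member of the Notch pathway. The MAPK list was drawn up for the output of the kinase cascade in which BRAF acts. Its targeted members were ELK3, EPHA2, EREG, ETV4, JUN and MYC, and whether the cascade induces each of them was not examined.

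Few genes of the melanocyte lineage list were targeted. Of the 27 in the list, 3 had a probe, namely CEACAM1, ERBB3 and MCAM. Being listed does not by itself make a gene specific to the lineage. No probe matched MITF, the master regulator of the lineage, or the pigment genes TYR, DCT and PMEL. The undifferentiated melanoma list had 17 of 31 genes, including EGFR, WNT5A and SOX9. Of the cell cycle list, 3 of 41 genes had a probe, the inhibitors CDKN1A and CDKN2A and the tumour suppressor RB1. Iron handling, the process for which the transferrin family is known, had 2 of 17, TF and HMOX1. It was the 1 list with fewer than 3 targeted members. Among markers of other cell types, 18 of 32 endothelial and 6 of 33 leukocyte genes had a probe. The reference gene list had 31 of 45, the 30 housekeeping rows and PGK1, a glycolytic gene that the panel classes as endogenous. Since this list held all the panel's housekeeping genes, its share cannot be read as coverage like that of the other lists.

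**Figure D1:**
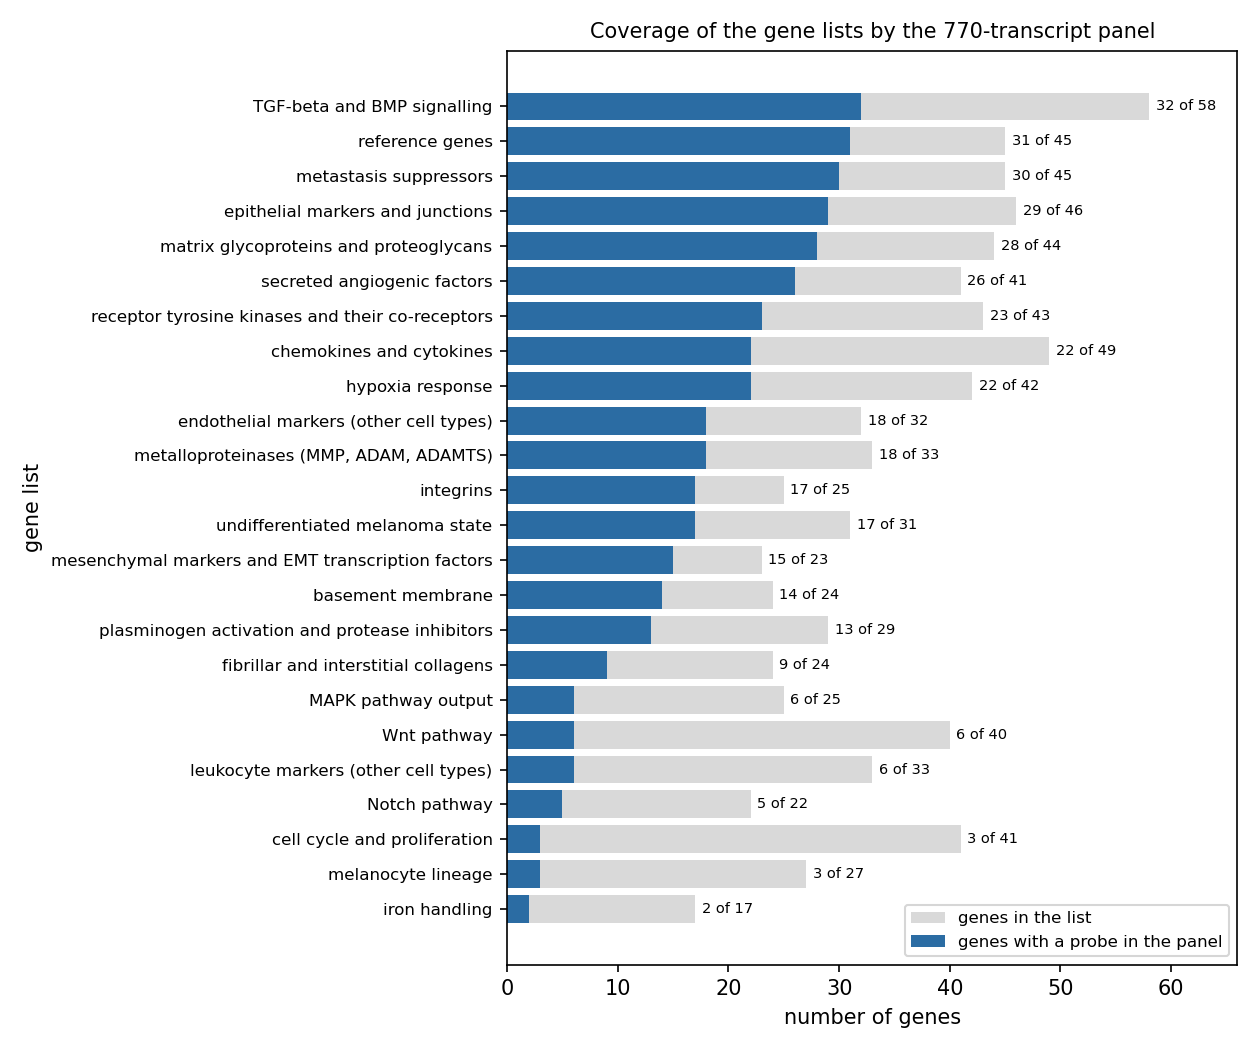
Horizontal bars give the number of genes in each of the 24 lists (grey) and the number with a probe in the panel (blue), both on a linear axis from 0. The number of genes with a probe runs from 32 of 58 for TGF-beta and BMP signalling to 2 of 17 for iron handling, and the share of the list from 68.9% for reference genes to 7.32% for cell cycle and proliferation.

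Each gene was read by a target of 100 bases. No pair among the 770 targets shared an exact stretch of 25 bases or more. Targets that are similar but broken by mismatches would not be found by this criterion. Matches to transcripts outside the panel were not searched. They bear on ANXA2P2, named here outside the lists, which is annotated as a transcribed pseudogene of the annexin family and was targeted while ANXA2 had no probe. The GC content of the endogenous targets ranged from 32.0%, in AREG, to 75.0%, in TWIST1, with a median of 49.0%. The housekeeping targets had a median of 47.0% and ranged from 42.0% to 55.0%. The ranges are not comparable, since they cover 30 housekeeping and 740 endogenous targets and fewer targets tend to span less.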

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

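None of the other settings fixed in advance was run, since each of them refits a comparison between the lines and no column of values was used. They cover the pseudocount, the filter on low values, the normalization, the variance model, the samples in the fit, leaving out each sample in turn, the fold threshold, the count tests and the gene list tests. No paired analysis was possible because the columns of values carry no replicate number that a label ties to a sample. The settings tried on the panel's text columns were all chosen after seeing the data. With a stretch of 20 bases, or on either strand, 0 pairs of targets shared sequence, and with a stretch of 15 bases 5 pairs did, the longest stretch being 16 bases. Searching for MELTF under any synonym also gave 0 rows. For the 24 lists, 48 counts were made again. They matched only the first symbol of each list entry to the deposited symbol, or used endogenous rows alone. Of these counts, 45 were identical. By first symbol, the metastasis suppressor list had 29 genes and the secreted angiogenic factor list 25. Their deposited symbols MED23 and FIGF stood second in the list entries. Over endogenous rows alone the reference gene list had 1.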
